A study of Homo sapiens with 15 samples.

How the data were processed

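RNA from A549 cells, an established human lung adenocarcinoma line, was sequenced in 15 libraries from 5 groups of 3. One group received the solvent dimethyl sulfoxide (DMSO) and the other 4 received fine particulate matter (PM2.5) at 100 µg/mL for 24 h. The PM2.5 groups carry the codes CDSUM, CDWIN, CQSUM and CQWIN, whose meaning is not given in the sources used here. The labels do not say whether the 3 libraries of a group came from separate cultures, so each p-value measures the spread between these libraries only.

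The authors deposited 1 table with 58735 genes. It holds the deposited raw counts of reads per gene and the deposited FPKM values per library. It also holds the authors' results for 8 comparisons: mean signal per group, log2 fold change, p-value and adjusted p-value. The deposited table further gives gene length in bases and an annotation. The aligner and the counting program are not given, the strand of the libraries is not stated, and the labels name 2 different library kits. Reads of genes that overlap on opposite strands can therefore be shared. Among the genes named, an overlap of this kind with another tested gene was found for CEBPZ, ID4, CEMIP, CYP1B1, DDIT3, TIPARP, TXNRD1, HSP90B1, KIF23, MCM2, THBS1, COL4A1, RPL5, RPS23, KRT18, KRT8, SLC16A6, GREM1, IFIT1, SAMD11, STARD4, RPS6, ABCA3, FADS1, RECQL, RAD17 and MAP3K3. AHRR, TXNRD1, GDF15 and MT-ND4 overlap a tested gene on the same strand. The labels name mouse genome builds. All 58735 gene identifiers are human Ensembl identifiers found in GENCODE release 29, and 58724 have the same start and end there, so coordinates are given on GRCh38.

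The raw counts were the input. Total counts ran from 17583532 to 19216323 reads per library. Genes were kept with the filterByExpr function of edgeR 4.0.16 in R 4.3.3, which left 15565 of the 29725 genes with at least 1 read. The genes removed held 0.0838% of the reads. Library sizes were scaled by the trimmed mean of M-values (TMM). A single edgeR quasi-likelihood model had 1 coefficient per group and 10 residual degrees of freedom. The common biological coefficient of variation was 20.5%. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested. Fold changes are the first group over the second, and expression is in TMM-scaled CPM, the counts scaled to a common library size. Errors of CPM are SD and errors of log2 fold changes are SE. This SE was derived as the absolute log2 fold change over the square root of the F statistic of its test.

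There were 9 contrasts: each PM2.5 group against DMSO, CDWIN against CDSUM, CQWIN against CQSUM, CDSUM against CQSUM, CDWIN against CQWIN, and the interaction, which is the CDWIN minus CDSUM difference less the CQWIN minus CQSUM difference. Genes called in 1 direction in all 4 comparisons with DMSO were counted as well.

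The contrasts, 25 gene lists and the rule for naming genes were fixed before the data were examined. For each comparison with DMSO the rule names the 8 genes per direction with the largest change. These had to be called, protein coding, at a mean of at least 5 CPM in the higher group, and with no overlap between the libraries of both groups. It also names up to 4 called members per list and 12 genes whatever their result: CYP1A1, CYP1B1, AHRR, HMOX1, NQO1, IL6, CXCL8, IL1B, MT2A, DDIT3, CDKN1A and HMGCS1. For the other contrasts it names 5 genes per direction and the same 12. The text gives a part of these genes.

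The lists cover aryl hydrocarbon receptor targets, NRF2 targets, metallothioneins, inflammatory genes, interferon-stimulated genes, the unfolded protein response, heat shock, p53 targets, the cell cycle, DNA replication, cholesterol synthesis, fatty acid synthesis, hypoxia, epithelial-mesenchymal transition, ribosomal proteins, nuclear and mitochondrial genes of oxidative phosphorylation, autophagy, iron handling, apoptosis, complement, immediate early genes, and epithelial, leukocyte and fibroblast or endothelial markers. The 24 lists with at least 3 measured genes were tested with camera of limma 3.58.1 on log CPM with a prior count of 2. The preset correlation between genes was 0.01, and each test was repeated with an estimated correlation. Adjustment was over the lists within a contrast. Calls of list members are given over all genes tested and adjusted over the list alone.

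Choices varied from the start were the size factors of DESeq2, DESeq2 1.42.0 itself, no filter on low counts, a filter of 5 CPM in 3 libraries, a block by replicate number, a fit on the compared groups only, an estimated correlation for list tests, and leaving out each library. Alternatives added after seeing the data removed trends with GC content, with length or with both. These used 1 transcript per gene and natural splines with 6 degrees of freedom per library. Another left out CDWIN 2 and CQWIN 3. A further one compared only libraries on 1 side of the GC trend, by leaving out CDWIN libraries, with all other groups kept in the fit. The last kept CDWIN 1 or CDWIN 3 as the only CDWIN library. A group with 1 library has no spread of its own, which the model takes from the other groups. The replicate numbers did not clearly pair the libraries: across 30 pairs with the same number, correlations of the residuals across genes ran from −0.414 to 0.395. Their median was 0.0496, against −0.0277 for pairs with different numbers, and 9 of the 15 libraries correlated best with their own number. A partial pairing is therefore left open.

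The model was tested on simulated data with the same spread. For CDSUM against DMSO, 17.9% of genes changed 1.5-fold, 56.7% of genes changed 2-fold and 97% of genes changed 4-fold were recovered, with 4 false calls. For the interaction the shares were 1.49%, 20.9% and 69.7%. These simulations held no trend, were run a single time each and changed 200 genes drawn from those above a minimum mean count. The shares therefore do not cover genes with low counts. When a GC and length trend was added to the simulated CQSUM libraries, CDSUM against CQSUM had 2726 false calls, 95.1% of its calls, and 3 once the trends were removed. The added trend was the same in all 3 CQSUM libraries and used the GC and length values that the removal fits. It therefore does not tell how well the removal works on the real libraries. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. The FPKM values and the authors' mean signal per group were not analysed here.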

Results

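Gene expression was measured by RNA sequencing in A549 cells after 24 h with DMSO or with PM2.5 at 100 µg/mL under 1 of 4 codes, CDSUM, CDWIN, CQSUM or CQWIN. Each of the 5 groups had 3 libraries, numbered 1 to 3. The smallest library, CQWIN 3, held 17583532 reads and the largest, CQSUM 1, held 19216323.

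The libraries differed in how counts depended on the GC content and the length of genes. The GC slope was positive in all 3 DMSO libraries (0.16 to 0.347 log2 units per 10 percentage points) and in all 3 CDSUM libraries (0.138 to 0.206). It was negative in the other 3 groups, from −0.0972 to −0.226, except in CDWIN 2 at 0.125. The length slope was 0.127 to 0.248 log2 units per doubling in DMSO and negative in all 6 CDSUM and CDWIN libraries. CQWIN 3, at 0.228, was within the DMSO range, whereas CQWIN 1 was at −0.125. The first principal component held 37.9% of the variance and the second 22.3%. Short transcripts and GC-poor or GC-rich transcripts moved with these slopes, so values with both trends removed are given for those named genes and lists where they differed most. The slopes ran partly along the groups, and removing the trends can also remove real change.

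**Figure D1:**
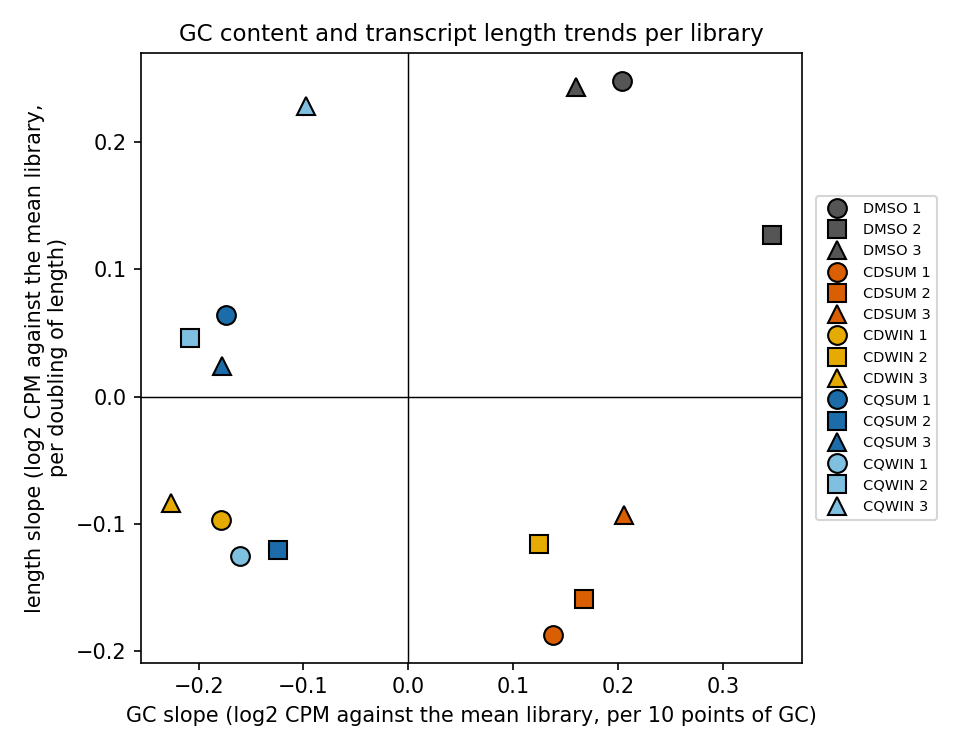
GC slope (log2 units per 10 percentage points of GC, x axis) against length slope (log2 units per doubling of transcript length, y axis) for each of the 15 libraries, with colour for the group and marker for the replicate number. CDWIN 2 lies at a GC slope of 0.125, apart from CDWIN 1 and CDWIN 3, and CQWIN 3 lies at a length slope of 0.228.

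The comparison of CDSUM with DMSO asked how this PM2.5 changed the transcriptome of A549 cells. CYP1A1, a cytochrome P450 induced through the aryl hydrocarbon receptor, rose 31.8-fold (log2 fold change 4.99 ± 0.45), from 0.493 ± 0.329 to 15.8 ± 3.53 CPM (n = 3 per group). The neutrophil chemokine CXCL8 rose 6.83-fold (2.77 ± 0.26), from 97.8 ± 12.3 to 668 ± 120 CPM, and INSIG1, a regulator of sterol synthesis, rose 5.76-fold (2.53 ± 0.17), from 8.73 ± 0.694 to 50.3 ± 9.9 CPM. ID4, an inhibitor of DNA binding, was 8.85-fold lower (−3.15 ± 0.35), at 1.52 ± 0.328 against 13.5 ± 2.31 CPM. CYP1A1 is ENSG00000140465, on chromosome 15 from 74719542 to 74725610. CXCL8 lies on chromosome 4 from 73740506 to 73743716, and ID4 on chromosome 6 from 19837386 to 19840684.

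Other large increases in CDSUM were in the growth factor gene CSF2 (11.2-fold), in ANXA10 (8.25-fold), in the cytokine genes IL1B (7.1-fold) and CCL20 (7.09-fold), and in SCG5 (7.08-fold). CSF2 was 6.4-fold, CCL20 4.65-fold and SCG5 4.24-fold higher with GC and length trends removed. SPTSSB had the largest fold of the named genes, 52.9, through CDSUM 3 at 31.6 CPM, whereas CDSUM 1 and 2 were at 0.658 and 0.871 CPM. Without CDSUM 3 its log2 fold change was 1.89 and it was not called. Beside ID4, the largest decreases were in CEBPZ, KNTC1, TOP2A, MCM8, SUSD2, DZIP3 and CEMIP, from −3.25 to −3.03 on the log2 scale. CEMIP was at −4.16 without CDSUM 3, and KNTC1 was 5.72-fold lower with both trends removed, against 8.8-fold as tested. CEBPZ overlaps NDUFAF7 and CEBPZOS on the opposite strand. TOP2A, a DNA topoisomerase of dividing cells, averaged 26.7 ± 2.31 CPM against 234 ± 130 in DMSO, where DMSO 2 was the lowest at 89 CPM.

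Of the 9 aryl hydrocarbon receptor targets measured, 4 rose and 2 fell in CDSUM, both over all genes and adjusted over the list alone. CYP1B1 rose 3.52-fold, TIPARP 4.02-fold and the quinone reductase gene NQO1 2.1-fold. The receptor's repressor AHRR, which overlaps PDCD6 on the same strand, was not called (0.61 ± 0.36), but it was with GC and length trends removed (1.16). Camera gave this list an adjusted p = 0.0101, and adjusted p = 0.335 with an estimated correlation. Its median was 0.61, or 1.00 with both trends removed. Of 26 inflammatory genes, 14 rose and 2 fell, or 16 and 2 adjusted over the list alone (median 0.73, adjusted p = 3.93e-07, and adjusted p = 0.231 with an estimated correlation). CCL2 rose 3.43-fold, or 2.16-fold with both trends removed, and IL6 3.79-fold. Of 18 immediate early genes, 7 rose and 1 fell, with the same counts adjusted over the list alone. Camera gave them an adjusted p = 0.0101, and adjusted p = 0.407 with an estimated correlation, but the call was lost without CDSUM 3 (median 0.05). IER3 rose 3.78-fold (1.92, and 1.32 with the length trend removed) and ATF3 6-fold.

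Cholesterol synthesis genes rose in CDSUM: 11 of 23 were higher and none lower, with the same counts adjusted over the list alone (median 0.32, adjusted p = 9.57e-06, and adjusted p = 0.231 with an estimated correlation). FDFT1, which makes squalene, rose 2.12-fold and MSMO1 1.85-fold. HMGCS1 was higher by only 0.46 ± 0.19 (adjusted p = 0.0486). Its value with both trends removed was 0.72 ± 0.15 (adjusted p = 0.0017). As tested, HMGCS1 was not called without DMSO 1 (0.45), DMSO 2 (0.43), DMSO 3 (0.52), CDSUM 1 (0.39) or CDSUM 3 (0.38). The lipid droplet gene PLIN2 rose 4.09-fold, whereas ACLY, which makes acetyl-CoA for lipid synthesis, was 2.36-fold lower.

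Genes of cell division fell in CDSUM. Of 25 cell cycle genes 19 were lower and none higher, with the same counts adjusted over the list alone (median −1.12, adjusted p = 0.000303, and adjusted p = 0.407 with an estimated correlation). The mitotic kinesins KIF11 and KIF23 were 6.09-fold and 5.08-fold lower and the checkpoint kinase gene BUB1B 3.28-fold lower. Of 25 DNA replication genes 18 were lower and none higher, again the same adjusted over the list alone (median −0.63, adjusted p = 0.000975, and adjusted p = 0.407 with an estimated correlation). The helicase subunit genes MCM5 and MCM2 were 2.37-fold and 2.16-fold lower.

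Stress genes in CDSUM split. DDIT3, a transcription factor of endoplasmic reticulum stress, rose 5.01-fold, or 3.17-fold with both trends removed, whereas the chaperone gene HSP90B1 was 3.03-fold lower. Of 22 unfolded protein response genes 8 rose and 7 fell, the same adjusted over the list alone (adjusted p = 0.145). Of 14 heat shock genes 1 rose and 9 fell, the same adjusted over the list alone (adjusted p = 0.0227, and adjusted p = 0.335 with an estimated correlation), but the call was lost without CDSUM 3 (median −0.87). HSPA1A and HSPA1B, 2 nearly identical genes whose reads are hard to tell apart, were 3.3-fold and 3.26-fold lower. Of 25 NRF2 targets 10 rose and 7 fell, or 10 and 8 adjusted over the list alone (adjusted p = 0.119). The thioredoxin gene TXN rose 2.91-fold, or 1.81-fold with both trends removed, and TXNRD1, which overlaps EID3 on the same strand, rose 1.88-fold. HMOX1, the inducible heme oxygenase gene, was not called (−0.32 ± 0.14), but it was with both trends removed (−0.47). CDKN1A was not called either (0.05 ± 0.15). The p53 target list had 2 genes higher and 5 lower of 22, or 2 and 4 adjusted over the list alone (adjusted p = 0.74). GDF15 rose 2.44-fold (1.29, and 0.68 with the length trend removed).

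Among structural and metabolic genes, 27 of 31 ribosomal protein genes rose in CDSUM and none fell, or 29 and none adjusted over the list alone (median 0.84, adjusted p = 8.95e-13, and adjusted p = 0.407 with an estimated correlation). With GC and length trends removed the median was 0.26 and 14 rose and 1 fell. Of 28 nuclear genes of oxidative phosphorylation 16 rose and 1 fell, the same adjusted over the list alone (median 0.53, or 0.17 with the trends removed). Their adjusted p was 3.93e-07, and adjusted p = 0.407 with an estimated correlation. Of 13 mitochondrially encoded genes 11 fell and 1 rose, the same adjusted over the list alone (median −1.19, adjusted p = 0.000785, and adjusted p = 0.407 with an estimated correlation). Their median with both trends removed was −1.91. MT-ND4 was 2.55-fold lower. Mitochondrial genes held 3.47% to 3.82% of the reads in CDSUM and 5.02% to 5.7% in DMSO. The keratin genes KRT8 and KRT18, which overlap each other on opposite strands and can share reads where the strand is not recorded, were 2.04-fold and 2.12-fold lower. Of 11 epithelial markers 2 rose and 6 fell, the same adjusted over the list alone (adjusted p = 0.275). MT2A, a metallothionein gene, was higher by 0.72 ± 0.20, but by 0.07 and not called with both trends removed, at −0.11 with the length trend removed, and it was not called without DMSO 1 (0.59).

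In the CDSUM comparison edgeR called 7239 of 15565 genes, 2381 higher and 4858 lower, of which 3040 changed at least 2-fold. The median of all genes was −0.25 on the log2 scale, and −0.10 with the size factors of DESeq2. The share of called genes that rose was 32.9% under TMM, 45.1% under those size factors and 50.9% without a filter on low counts. With GC and length trends removed 5997 genes were called, and 4650 genes kept their call.

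CDWIN against DMSO asked the same of the CDWIN PM2.5. CYP1A1 rose 24.8-fold (4.63 ± 0.45), to 12.3 ± 2.31 CPM (n = 3), TIPARP 5.35-fold (2.42 ± 0.20) and CXCL8 6.95-fold (2.80 ± 0.26), to 679 ± 93 CPM, or 4.18-fold with GC and length trends removed. MSMO1, a sterol oxidase gene of cholesterol synthesis, rose 3.55-fold (1.83 ± 0.19), from 21.5 ± 0.211 to 76.2 ± 15.1 CPM. ID4 was 18.5-fold lower (−4.21 ± 0.38), at 0.72 ± 0.432 CPM, and the neuronal pentraxin gene NPTX1 10.8-fold lower (−3.43 ± 0.33), or 6.85-fold with both trends removed. Without CDWIN 3 the value of ID4 was −4.81.

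Further increases in CDWIN were in ANXA10 (10.2-fold), SLC16A6 (9.23-fold), CSF2 (8.84-fold), IL1B (8.32-fold), GREM1, an antagonist of bone morphogenetic proteins (7.71-fold), and SCG5 (7.21-fold). BOLA2B was called at 14.3-fold through CDWIN 2 at 145 CPM, with 7.27 and 6.83 CPM in the other 2 libraries. Its log2 fold change without CDWIN 2 was 0.93 and it was not called. Beside ID4 and NPTX1 the largest decreases were in FSTL4, FGFR3, EDN2, SUSD2, RNF43 and AXIN2, from −3.19 to −2.82. ANXA10 was 5.85-fold and CSF2 5.66-fold higher with both trends removed, and FGFR3 5.59-fold lower against 8.93-fold as tested. FGFR3 was at −3.79 without CDWIN 3. CSF2 (3.14) was at 2.46 and SCG5 (2.85) at 2.14 with the length trend removed. SLC16A6 (3.21) was at 2.43, GREM1 (2.95) at 2.24, EDN2 (−3.04) at −2.31, RNF43 (−2.86) at −3.99 and BOLA2B (3.84) at 5.29 with CDWIN 2 as the only CDWIN library, and ID4 (−4.21) at −4.96. RNF43 and AXIN2 are feedback inhibitors of Wnt signalling.

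Cholesterol synthesis was the list with the smallest p after ribosomal proteins in CDWIN: 17 of 23 genes rose and none fell, the same adjusted over the list alone (median 0.84, adjusted p = 5.87e-09, and adjusted p = 0.0524 with an estimated correlation). INSIG1 rose 5.31-fold, IDI1 2.96-fold (1.57, and 1.04 with both trends removed) and HMGCS1 2.7-fold. Of 26 inflammatory genes 13 rose and 3 fell, the same adjusted over the list alone (adjusted p = 0.00047, and adjusted p = 0.481 with an estimated correlation), with a median of 0.54, or 0.30 with both trends removed. CCL2 rose 3.72-fold, or 1.78-fold with them removed. IL6 rose 2.98-fold but was not called with GC and length trends removed (0.93). Of 9 aryl hydrocarbon receptor targets 4 rose and 1 fell, the same adjusted over the list alone (adjusted p = 0.0563), CYP1B1 3.85-fold and NQO1 1.92-fold. That list was called with both trends removed (adjusted p = 0.00249, and adjusted p = 0.467 with an estimated correlation). AHRR was not called (0.34), but it was with both trends removed (1.04). Of 26 epithelial-mesenchymal transition and matrix genes 15 fell and 1 rose, the same adjusted over the list alone (adjusted p = 0.012, and adjusted p = 0.481 with an estimated correlation), a call lost with both trends removed (median −0.50). COL4A1, a basement membrane collagen gene, was 3.01-fold lower, or 1.86-fold with both trends removed, and THBS1 2.74-fold lower.

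In CDWIN 9 of 25 cell cycle genes fell and 1 rose, the same adjusted over the list alone (adjusted p = 0.136), with PLK1, a mitotic kinase gene, 2.04-fold lower. Of 25 DNA replication genes 12 fell and none rose, the same adjusted over the list alone (adjusted p = 0.0522), with MCM5 2.31-fold lower (−1.21, and −0.75 with both trends removed). The cell cycle list (adjusted p = 0.000564, and adjusted p = 0.524 with an estimated correlation) and the DNA replication list (adjusted p = 0.000695, and adjusted p = 0.519 with an estimated correlation) were called lower with both trends removed. HSPA1A was 3.72-fold lower and DDIT3 rose 3.5-fold. Of 31 ribosomal protein genes 27 rose and none fell, or 29 and none adjusted over the list alone (adjusted p = 1.58e-10, and adjusted p = 0.481 with an estimated correlation). Their median was 0.87, or 0.44 with both trends removed. Of 21 interferon-stimulated genes 3 rose and 1 fell, or 2 and 1 adjusted over the list alone (adjusted p = 0.199), with IFIT1 2.26-fold higher, but not called with both trends removed (0.58). Of 21 hypoxia and glycolysis genes 9 rose and 4 fell, the same adjusted over the list alone (adjusted p = 0.372). LDHA, which makes lactate, rose 1.8-fold (0.84, and 0.41 with both trends removed). HMOX1 was lower (−0.43 ± 0.14), but not called without DMSO 2 (−0.36), DMSO 3 (−0.43), CDWIN 1 (−0.42) or CDWIN 3 (−0.35). MT2A was higher by 0.72 ± 0.20, but not called without DMSO 1 (0.59) or with both trends removed (0.33). CDKN1A was not called (−0.19).

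CDWIN against DMSO had 6493 genes called by edgeR, 2869 higher and 3624 lower, of which 2334 changed at least 2-fold. The balance was 3168 higher and 3056 lower with the size factors of DESeq2 and 3348 and 2671 with the GC trend removed. After removal of the GC and length trends 4558 were called, and 3575 kept their call. With a single CDWIN library, assumed to vary like the libraries of the other groups, the count was 3785 for CDWIN 1, 1488 for CDWIN 2 and 4250 for CDWIN 3. PLK1 (−0.71), IL6 (0.71), NQO1 (0.87), LDHA (0.68), HMOX1 (−0.26) and MT2A (0.85) were not called with CDWIN 2 as the only CDWIN library, and PLK1 was called with CDWIN 1 (−1.31) or CDWIN 3 (−1.12) as the only one.

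The question for CQSUM against DMSO was the same. CYP1A1 rose 22-fold (4.46 ± 0.45), to 10.9 ± 1.71 CPM (n = 3), TIPARP 6.17-fold (2.62 ± 0.20), to 107 ± 15 CPM, and CYP1B1 4.77-fold (2.26 ± 0.24). CXCL8 rose 5.16-fold (2.37 ± 0.25), to 505 ± 95.6 CPM, or 3.1-fold with GC and length trends removed, and INSIG1 5.67-fold (2.5 ± 0.17), to 49.6 ± 0.651 CPM. ID4 was 11.9-fold lower (−3.57 ± 0.36) and the sushi domain gene SUSD2 8.4-fold lower (−3.07 ± 0.31), or 5.46-fold with both trends removed.

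CSF2 (10.9-fold), GREM1 (8.46-fold), ANXA10 (7.09-fold), IL1B (6.7-fold), SLC16A6 (5.96-fold) and the retinol dehydrogenase gene DHRS9 (5.84-fold) rose as well in CQSUM. NPTX1, CEMIP, AXIN2, FGFR3, FSTL4 and SAMD11 fell, from −3.02 to −2.59 on the log2 scale. ANXA10 was 4.29-fold higher with both trends removed, NPTX1 5.23-fold lower against 8.1-fold as tested, and FGFR3 4.23-fold lower against 6.91-fold.

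Of 26 inflammatory genes 12 rose and 2 fell in CQSUM, or 13 and 2 adjusted over the list alone (adjusted p = 0.000195, and adjusted p = 0.35 with an estimated correlation). CCL2 rose 3.75-fold, or 2.04-fold with both trends removed. IL6 rose 3.07-fold but was not called with GC and length trends removed (1.10). Of 23 cholesterol synthesis genes 14 rose and none fell, or 15 adjusted over the list alone (median 0.56, adjusted p = 6.58e-07, and adjusted p = 0.107 with an estimated correlation). STARD4, a sterol carrier gene, rose 3.37-fold, MSMO1 3.08-fold (1.62, and 1.06 with both trends removed) and HMGCS1 2.36-fold. Of 9 aryl hydrocarbon receptor targets 4 rose and 1 fell, the same adjusted over the list alone (adjusted p = 0.0381, and adjusted p = 0.46 with an estimated correlation), a call lost without CQSUM 1 (median 0.29). NQO1 rose by 0.63 ± 0.23 (adjusted p = 0.0435). It was not called without DMSO 1 (0.61), DMSO 2 (0.71), DMSO 3 (0.57), CQSUM 2 (0.49) or CQSUM 3 (0.67), nor with both trends removed (0.50). AHRR was not called (0.26).

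Of 25 DNA replication genes 11 fell and none rose in CQSUM, the same adjusted over the list alone (adjusted p = 0.0213, and adjusted p = 0.542 with an estimated correlation), a call lost without CQSUM 1 (median −0.25). MCM5 was 2.32-fold lower (−1.21, and −0.73 with both trends removed) and CDT1, which licenses replication origins, 2.23-fold lower, or 1.45-fold with the trends removed. Of 25 cell cycle genes 4 fell and 1 rose, or 4 and none adjusted over the list alone (adjusted p = 0.267), a list called lower with both trends removed (adjusted p = 0.000737, and adjusted p = 0.542 with an estimated correlation). Of 13 mitochondrially encoded genes 6 fell and none rose, or 9 adjusted over the list alone (median −0.52, adjusted p = 0.00163, and adjusted p = 0.542 with an estimated correlation), with MT-ND1 2.59-fold lower. The median was −1.13 with both trends removed. Of 31 ribosomal protein genes 10 rose and none fell, the same adjusted over the list alone (adjusted p = 2.49e-05, and adjusted p = 0.542 with an estimated correlation). With both trends removed the median went from 0.51 to 0.30 and 12 rose, and RPL5 (0.78 to 0.22) and RPL11 (0.60 to 0.13) were not called. RPS6 was higher by 0.64, but by −0.01 with both trends removed, and it was not called without DMSO 1 (0.59), DMSO 3 (0.62) or CQSUM 2 (0.52). The matrix list had 11 genes lower and 1 higher of 26, or 14 and 1 adjusted over the list alone (adjusted p = 0.0316, and adjusted p = 0.542 with an estimated correlation). Its call was lost without DMSO 3 (median −0.49), without CQSUM 2 (−0.54) and with both trends removed (−0.30). FN1, the fibronectin gene, was 2.83-fold lower. Of 6 metallothionein and zinc genes 1, MT1F, rose (2.05-fold), the same adjusted over the list alone (adjusted p = 0.267). MT2A was not called (0.50), but it was without DMSO 2 (0.75). The keratin genes KRT8 and KRT18 were 2.05-fold and 2.09-fold lower, HMOX1 was lower by −0.53 ± 0.14 but not called with both trends removed (−0.29), and CDKN1A was not called (−0.21).

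In CQSUM against DMSO edgeR called 5061 genes, 2136 higher and 2925 lower, of which 1435 changed at least 2-fold. The share that rose was 42.2% under TMM and 52.3% under the size factors of DESeq2. After removal of the GC and length trends 2576 genes were called, 1417 higher and 1159 lower, and 1838 kept their call. Without DMSO 1 there were 3201 calls, and without CQSUM 2 there were 3049.

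CQWIN against DMSO again asked what the PM2.5 changed. INSIG1 rose 8.79-fold (3.14 ± 0.17), to 76.8 ± 1.57 CPM (n = 3), MSMO1 5.35-fold (2.42 ± 0.19) and HMGCS1, which starts the mevalonate pathway, 3.68-fold (1.88 ± 0.19), from 28.1 ± 1.87 to 104 ± 18 CPM. SCD, a fatty acid desaturase gene, rose 4.29-fold (2.10 ± 0.17), from 190 ± 18.2 to 813 ± 164 CPM. CYP1A1 rose 33.1-fold (5.05 ± 0.45), to 16.4 ± 7.87 CPM, and ID4 was 24.4-fold lower (−4.61 ± 0.39). INSIG1, CYP1A1 and ID4 were called with each library left out in turn.

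Of 23 cholesterol synthesis genes 22 rose in CQWIN and none fell, the same adjusted over the list alone (median 1.16, adjusted p = 5.35e-18). This call held with an estimated correlation (adjusted p = 0.00354), and the median was 1.24 with GC and length trends removed. Of 16 fatty acid and lipid storage genes 8 rose and 2 fell, the same adjusted over the list alone (adjusted p = 0.00633, and adjusted p = 0.388 with an estimated correlation), a call lost without CQWIN 3 (median 0.47). PLIN2 rose 5.83-fold and FADS1, a polyunsaturated fatty acid desaturase gene, 2.52-fold.

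SLC16A6 (11.9-fold), DHRS9 (9.28-fold), ANXA10 (8.69-fold), FGFBP1 (7.72-fold) and IL1B (7.6-fold) were among the other largest increases in CQWIN. Without CQWIN 1 SLC16A6 was at 2.79 and ANXA10 at 2.32 on the log2 scale, against 3.57 and 3.12, and ANXA10 was 5.43-fold higher with both trends removed. BOLA2B was called at 8.86-fold through CQWIN 3 at 87.3 CPM, with 6.32 and 4.81 CPM in the other 2 libraries. Its call was lost without CQWIN 3 (0.77), DMSO 1 (3.29), DMSO 2 (3.28) or DMSO 3 (2.90). NPTX1 was 12.6-fold lower, and EDN2, SUSD2, SAMD11, FGFR3, ANKRD2 and AXIN2 fell, from −3.25 to −2.47 on the log2 scale. SUSD2 (−3.05) was at −2.42, SAMD11 (−2.86) at −2.26 and FGFR3 (−2.50) at −1.82 with both trends removed.

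Of 9 aryl hydrocarbon receptor targets 4 rose and 1 fell in CQWIN, the same adjusted over the list alone (adjusted p = 0.00802, and adjusted p = 0.367 with an estimated correlation), with TIPARP 7.07-fold and CYP1B1 6.29-fold higher. AHRR was not called (0.65), but it was without CQWIN 2 (1.20) and with both trends removed (1.18). Of 26 inflammatory genes 11 rose and 2 fell, or 12 and 4 adjusted over the list alone (adjusted p = 0.00633, and adjusted p = 0.388 with an estimated correlation). CSF2 rose 6.32-fold, CXCL8 4.39-fold and IL6 2.75-fold. With both trends removed CXCL8 was 2.91-fold higher, IL6 was not called (1.09), and the median of the inflammatory list went from 0.54 to 0.36. Without CQWIN 3 neither list was called (medians 0.67 and 0.61). NQO1 was higher by 0.75 ± 0.23, but not called without DMSO 1 (0.73), DMSO 3 (0.69) or CQWIN 1 (0.32), nor with only the compared groups in the fit (0.77).

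DNA replication genes fell in CQWIN, 12 of 25 with none higher, or 14 adjusted over the list alone (adjusted p = 0.00199, and adjusted p = 0.408 with an estimated correlation), a call lost without CQWIN 3 (median −0.15). CDT1 was 2.67-fold lower, or 1.69-fold with both trends removed, and MCM5 2.63-fold lower. Of 25 cell cycle genes 6 fell and none rose, the same adjusted over the list alone (adjusted p = 0.0574), a list called lower with both trends removed (adjusted p = 7.16e-06, and adjusted p = 0.406 with an estimated correlation). Of 26 matrix genes 13 fell and 1 rose, or 14 and 1 adjusted over the list alone (adjusted p = 0.00199, and adjusted p = 0.388 with an estimated correlation), with COL5A1 3.12-fold lower, or 1.92-fold with both trends removed. Ribosomal protein genes had 3 higher and none lower of 31, or none adjusted over the list alone (median 0.35, adjusted p = 0.0095, and adjusted p = 0.69 with an estimated correlation). That call was lost without DMSO 1 (0.28), DMSO 3 (0.30) or CQWIN 1 (0.09). The 3 higher genes, RPL5 (0.63), RPS6 (0.56) and RPS23 (0.70), were at 0.13, −0.03 and 0.52 and not called with both trends removed, where 3 others, RPL3, RPS9 and RPS19, were, and the list median was 0.20. HMOX1 was lower (−0.67 ± 0.14), also with both trends removed (−0.39, adjusted p = 0.0397), but not called with the GC trend removed (−0.25). DDIT3 rose 2.94-fold, and MT2A (0.00) and CDKN1A (−0.22) were not called.

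CQWIN against DMSO had 4264 genes called by edgeR, 1804 higher and 2460 lower, of which 1168 changed at least 2-fold. The balance turned in some alternatives: 3866 were higher and 2236 lower without CQWIN 3, 2204 and 1246 without CQWIN 2, and 2176 and 2108 with the size factors of DESeq2. After removal of the GC and length trends 2329 were called, 1338 higher and 991 lower, and 1652 kept their call. The count was 2657 without DMSO 1, 2511 without CQWIN 1 and 6102 without CQWIN 3.

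**Figure D2:**
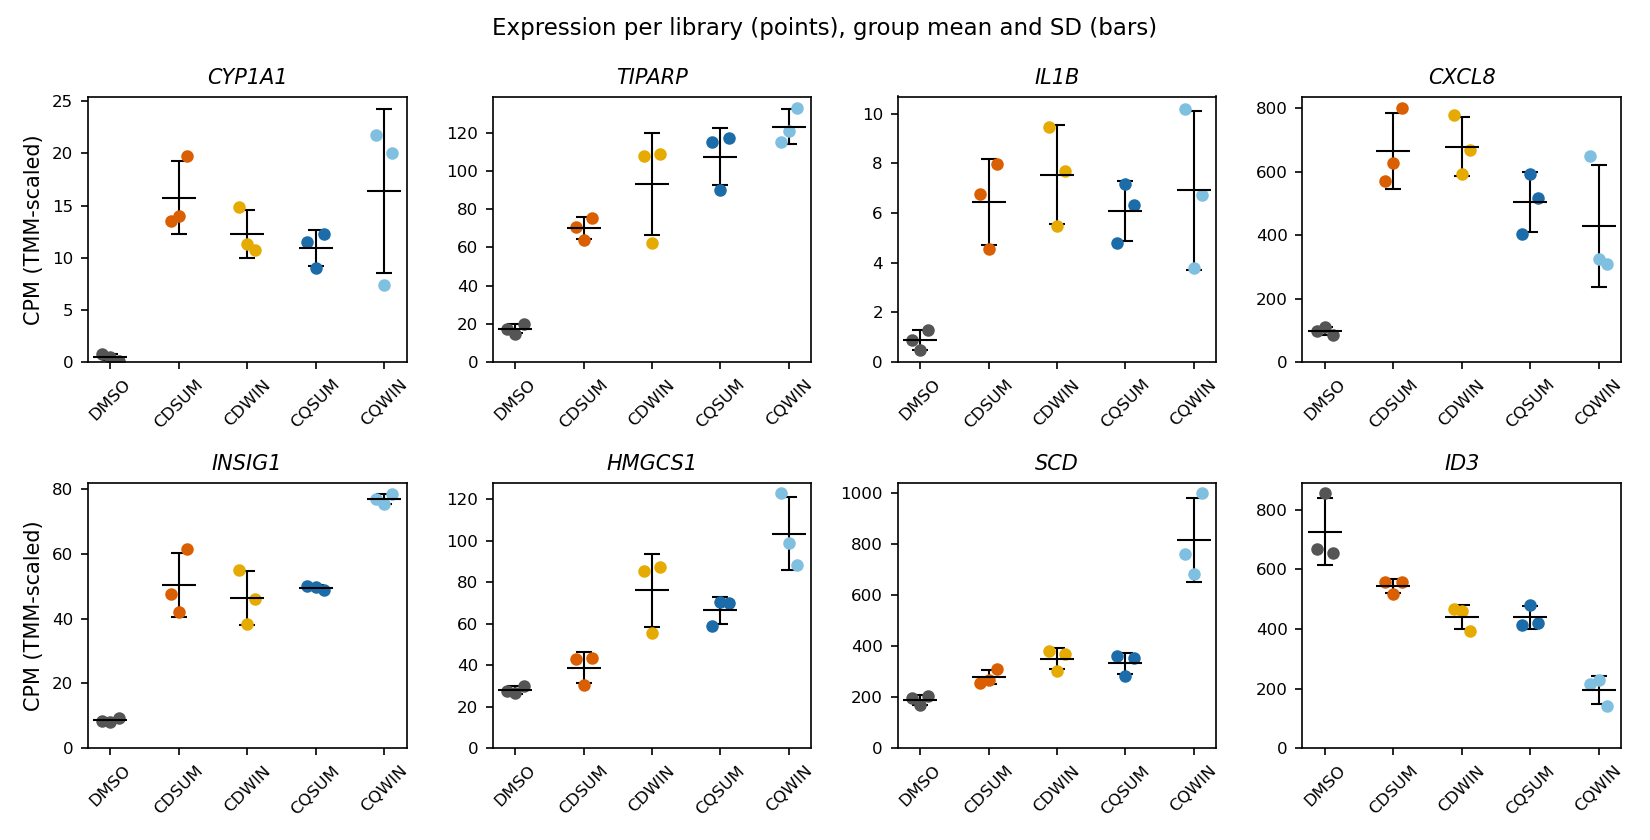
Expression in CPM (TMM-scaled, y axis) of CYP1A1, TIPARP, IL1B, CXCL8, INSIG1, HMGCS1, SCD and ID3 in each of the 5 groups (x axis), with a point per library and bars for the mean and SD of 3 libraries. INSIG1 averaged 8.73 CPM in DMSO and between 46.4 and 76.8 CPM in the 4 PM2.5 groups.

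**Figure D3:**
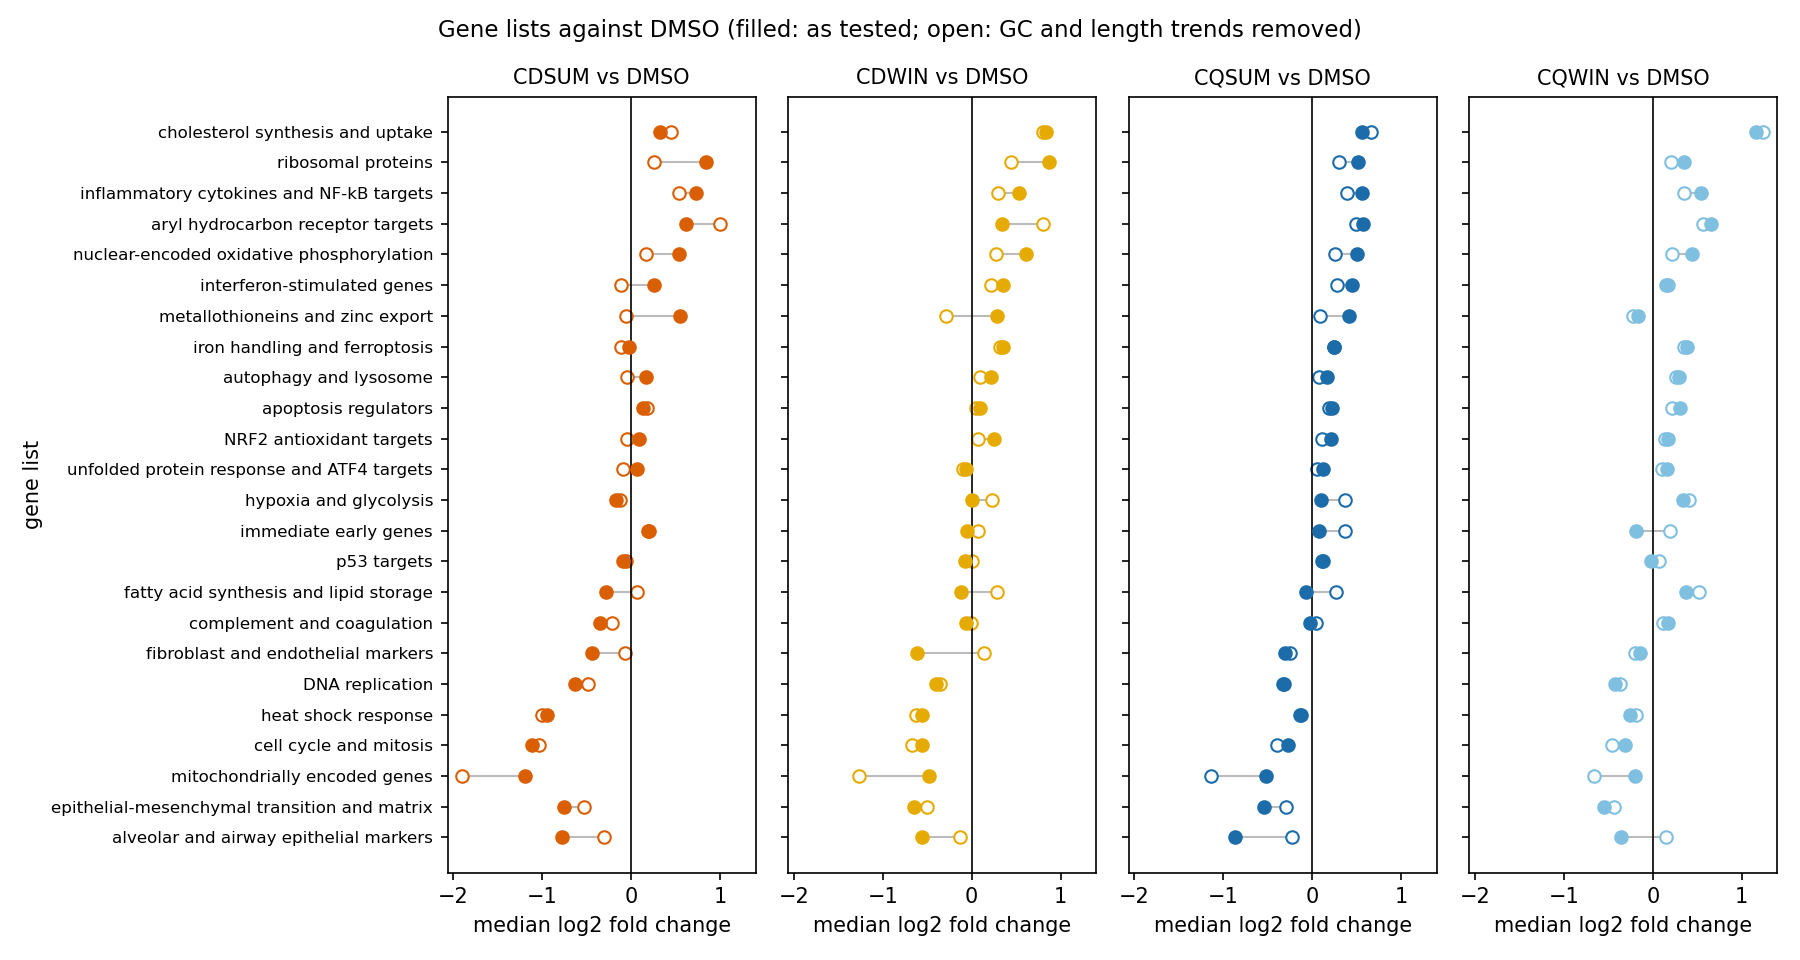
Median log2 fold change against DMSO (x axis) of the genes of each list (y axis) in the 4 PM2.5 groups, filled symbols as tested and open symbols with GC and length trends removed. The ribosomal protein median in CDSUM is 0.84 as tested and 0.26 with the trends removed, and the cholesterol median in CQWIN is 1.16 and 1.24.

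Across all 4 comparisons with DMSO, 2740 genes were called in a single direction, 923 higher and 1817 lower. They included CYP1A1, CYP1B1, TIPARP, CXCL8, IL1B, INSIG1 and HMGCS1 among the higher genes and ID4, SUSD2, MCM5, KRT8 and KRT18 among the lower. The 4 comparisons share the DMSO libraries. Independent lists of these sizes would share 6.98 higher and 33.6 lower genes. In 20 simulations all 15 libraries, DMSO included, were redrawn around the DMSO means without a GC or length trend, and edgeR called 0 genes in all 4. With no change and no trend simulated, a count near 0 was fixed in advance, so it is no chance level for the 2740 genes. The mean pairwise correlation of log2 fold changes across genes was 0.757, against 0.494 in those simulations. Genes are not independent replicates. With GC and length trends removed 1244 genes were called in all 4, 667 higher and 577 lower. The count was 1584 without DMSO 1 and 1783 without CQWIN 1. Without CQWIN 3 it was 3811, with 2463 higher and 1348 lower, and without CQWIN 2 there were 1383 higher and 701 lower. The size factors of DESeq2 gave 1193 higher and 1293 lower.

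CDWIN was compared with CDSUM to ask whether PM2.5 with the code CD acted differently under SUM and WIN. VPS35, a retromer subunit gene on chromosome 16, was 6.63-fold higher in CDWIN (2.73 ± 0.31), at 135 ± 63.1 against 20.4 ± 3.56 CPM (n = 3). The stress transcription factor gene ATF3 was 2.31-fold lower (−1.21 ± 0.33), at 5.07 ± 1.9 against 11.7 ± 5.14 CPM. VPS35 was at 83.8 to 115 CPM in the DMSO libraries. Its difference was 1.64 and not called with CDWIN 2 as the only CDWIN library, and 3.16 and 2.97, both called, with CDWIN 1 or CDWIN 3 as the only one. ATF3 was not called without CDSUM 3 (−0.79), CDWIN 2 (−1.07) or CDWIN 3 (−1.05), nor with both trends removed (−1.07). CYP1A1 (−0.36), CYP1B1 (0.13), CXCL8 (0.03), IL1B (0.23) and DDIT3 (−0.52) were not called.

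TTC21B (6.16-fold), KNTC1 (5.63-fold), WDR75 (5.46-fold) and DENND4C (5.22-fold) were the other largest increases in CDWIN. KNTC1 (2.03) and WDR75 (1.80) were not called without CDWIN 1, and TTC21B was 4.1-fold higher with both trends removed. IGFBP3, a carrier of insulin-like growth factors, was lower (−0.67), but not called without CDWIN 3 (−0.58) or with both trends removed (−0.46). HMGCS1 was 1.96-fold higher, but not called with both trends removed (0.45). Of 23 cholesterol synthesis genes 6 were higher and none lower, the same adjusted over the list alone (median 0.25, adjusted p = 0.00133, and adjusted p = 0.414 with an estimated correlation). Of 25 cell cycle genes 6 were higher and none lower, or 7 adjusted over the list alone (median 0.46, adjusted p = 0.000419, and adjusted p = 0.713 with an estimated correlation). Of 18 immediate early genes 2 were lower, or 4 adjusted over the list alone (median −0.41, adjusted p = 3.28e-06, and adjusted p = 0.414 with an estimated correlation). Of 13 mitochondrially encoded genes 3 were higher, or 5 adjusted over the list alone (median 0.31, adjusted p = 0.00147, and adjusted p = 0.713 with an estimated correlation), a call lost with both trends removed (0.30).

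In CDWIN against CDSUM edgeR called 1310 genes, 1272 higher and 38 lower, of which 802 changed at least 2-fold. After removal of the GC and length trends 673 were called, and 527 kept their call. With a single CDWIN library, assumed to vary like the libraries of the other groups, the count was 1064 for CDWIN 1, 2 for CDWIN 2 and 1131 for CDWIN 3. TTC21B (1.56), KNTC1 (1.65), WDR75 (1.40), DENND4C (1.65), HMGCS1 (0.52), ATF3 (−1.52) and IGFBP3 (−0.75) were not called with CDWIN 2 as the only one. The count was 554 without CDWIN 1, 578 without CDWIN 3, 857, 663 and 725 without CDSUM 1, 2 and 3, and 2187 without CDWIN 2 and CQWIN 3.

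The matching comparison for the code CQ was CQWIN with CQSUM. SCD was 2.44-fold higher in CQWIN (1.29 ± 0.17), at 813 ± 164 against 333 ± 41.5 CPM (n = 3, adjusted p = 0.00585). FADS1 was 1.83-fold higher (0.87 ± 0.14), at 444 ± 46.3 against 242 ± 12.5 CPM (adjusted p = 0.0454). ID3, an inhibitor of DNA binding like ID4, was 2.24-fold lower (−1.16 ± 0.18), at 196 ± 47.4 against 439 ± 37.4 CPM (adjusted p = 0.0227). SCD was not called without CQSUM 2 (1.19) or CQSUM 3 (1.33), nor ID3 without CQSUM 1 (−1.20), CQSUM 2 (−1.09) or CQSUM 3 (−1.20). FADS1 was not called without CQSUM 1 (0.87), CQSUM 2 (0.84), CQSUM 3 (0.91), CQWIN 1 (0.86) or CQWIN 3 (0.79). Cholesterol synthesis genes were higher as a list, with a median of 0.58: 0 of 23 passed over all genes and 19 passed adjusted over the list alone, all higher. Camera gave an adjusted p = 1.78e-26, and the call held with an estimated correlation (adjusted p = 0.000705). Of 16 fatty acid genes 2 were higher, or 8 adjusted over the list alone (median 0.44, adjusted p = 9.35e-14), which also held with an estimated correlation (adjusted p = 0.0156).

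Of 13 mitochondrially encoded genes none was called in CQWIN against CQSUM and 6 were higher adjusted over the list alone (median 0.39, adjusted p = 9e-07, and adjusted p = 0.28 with an estimated correlation). Of 6 metallothionein and zinc genes none was called and 3 were lower adjusted over the list alone (median −0.37, adjusted p = 0.00317, and adjusted p = 0.0546 with an estimated correlation), a call lost without CQWIN 1 (−0.45). Their median was −0.24 with both trends removed. For ribosomal proteins none was called either way (median −0.19, adjusted p = 1.81e-05, and adjusted p = 0.553 with an estimated correlation), and the median was 0.04 without CQWIN 3 and −0.12 with both trends removed. CYP1A1 (0.59), CXCL8 (−0.23), IL1B (0.18) and HMGCS1 (0.64) were not called.

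No further gene was called: edgeR called 3 in CQWIN against CQSUM, of 597 at an unadjusted p under 0.05. DESeq2 called 11 and edgeR called 12 with GC and length trends removed. The count of calls was 0 without CQSUM 2 or CQSUM 3 (341 and 557 at an unadjusted p under 0.05), 1 without CQSUM 1 and 11 without CQWIN 2.

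CDSUM was compared with CQSUM to contrast the codes CD and CQ within SUM. KNTC1, a kinetochore gene, was 8.31-fold lower in CDSUM (−3.06 ± 0.57), at 1.99 ± 0.286 against 16.6 ± 10.3 CPM (n = 3), and the DNA helicase gene RECQL was 8.31-fold lower (−3.05 ± 0.56). CEBPZ (−3.27), the checkpoint gene RAD17 (−3.02) and TTC21B (−2.97) completed the 5 largest decreases. KNTC1 was 4.98-fold, RECQL 5.08-fold, CEBPZ 6.26-fold, RAD17 5.48-fold and TTC21B 4.8-fold lower with GC and length trends removed. RECQL was at −2.26 without CQSUM 1. CEBPZ was called in every fit with a library left out except without CQSUM 1 (−2.25). SMIM11A had the largest increase, 8.52-fold, through CDSUM 2 at 32.5 CPM, with 1.74 and 2.34 CPM in the other 2 libraries. It was not called without CDSUM 2 (0.51) or CQSUM 3 (3.02). CYP1A1 (0.53), CYP1B1 (−0.44), CXCL8 (0.40), IL1B (0.08) and NQO1 (0.44) were not called, but CXCL8 was with both trends removed (0.80), and CYP1A1 (0.73), CXCL8 (0.61) and NQO1 (0.64) were without a filter on low counts.

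Of 25 cell cycle genes 10 were lower in CDSUM than in CQSUM and none higher, or 13 adjusted over the list alone (median −0.60, adjusted p = 0.00012, and adjusted p = 0.926 with an estimated correlation). Of 31 ribosomal protein genes none was called either way, though the list had a median of 0.34 (adjusted p = 3.34e-06, and adjusted p = 0.926 with an estimated correlation). That median was −0.04 and the list was not called with GC and length trends removed. Of 23 cholesterol synthesis genes 5 were lower and none higher, the same adjusted over the list alone (adjusted p = 0.409). HMGCS1 was 1.71-fold lower, but not called without CDSUM 2 (−0.62) or with both trends removed (−0.20).

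In CDSUM against CQSUM edgeR called 2156 genes, 26 higher and 2130 lower, of which 1477 changed at least 2-fold. With GC and length trends removed 453 were higher and 1305 lower. Of the 2156 called genes 1124 kept their call, 6 higher and 1118 lower. Without a filter on low counts 735 were higher and 1747 lower.

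**Figure D4:**
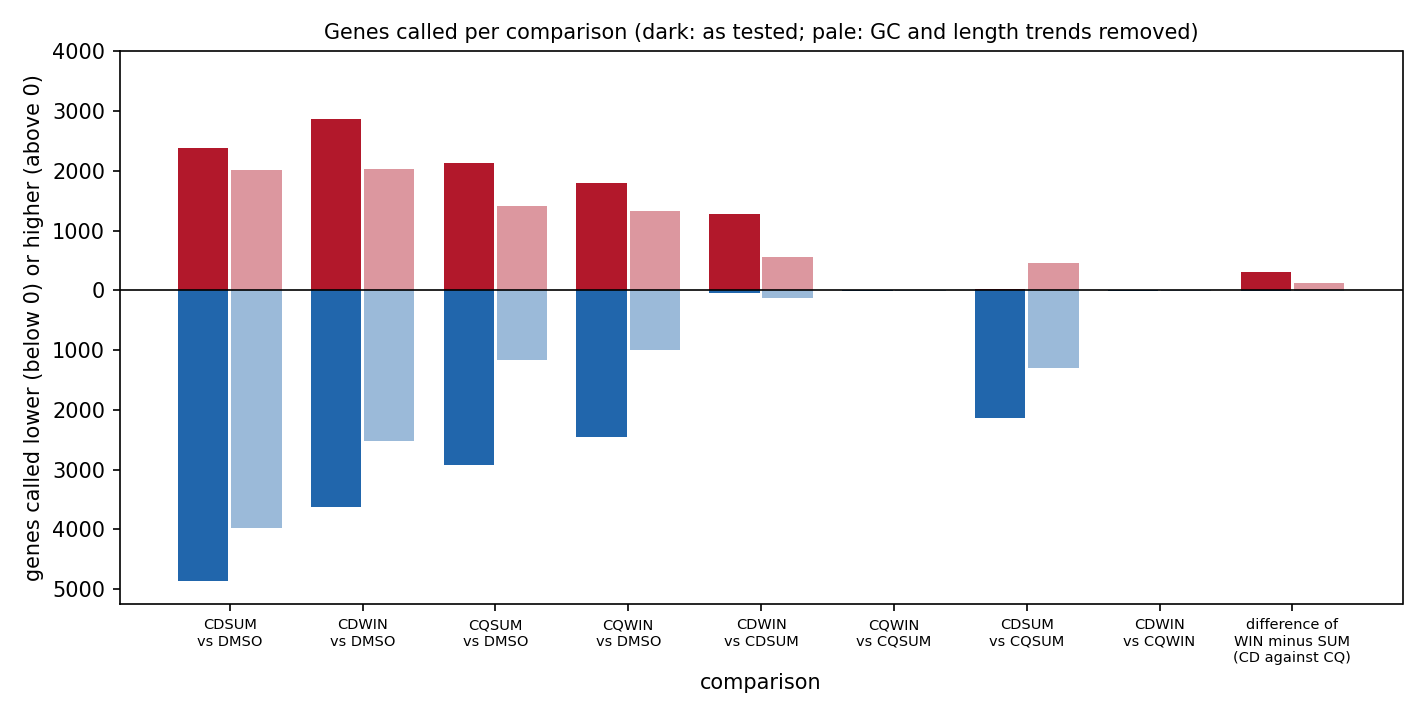
Number of genes called (y axis) higher (above 0) and lower (below 0) in each comparison (x axis), dark bars as tested and pale bars with GC and length trends removed. In CDSUM against CQSUM 26 genes are higher and 2130 lower as tested, and 453 are higher and 1305 lower with the trends removed.

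CDWIN against CQWIN contrasted the same codes within WIN. ID3 was 2.25-fold higher in CDWIN (1.17 ± 0.18), at 440 ± 40.7 against 196 ± 47.4 CPM (n = 3, adjusted p = 0.0218), and SCD 2.31-fold lower (−1.21 ± 0.17), at 351 ± 41.4 against 813 ± 164 CPM (adjusted p = 0.0137). Neither was called without CDWIN 1 (1.13 and −1.27), CDWIN 2 (1.13 and −1.12) or CDWIN 3 (1.24 and −1.25). Cholesterol synthesis genes were lower as a list (median −0.51, adjusted p = 2.15e-07, and adjusted p = 0.0987 with an estimated correlation). None of the 23 passed over all genes, and 14 were lower and 1 higher adjusted over the list alone. Of 16 fatty acid genes 1 was lower, or 5 adjusted over the list alone (median −0.36, adjusted p = 6.46e-06, and adjusted p = 0.237 with an estimated correlation). Ribosomal protein genes were higher as a list (median 0.59, adjusted p = 4.78e-16, and adjusted p = 0.722 with an estimated correlation), with none called over all genes and 20 higher adjusted over the list alone. Their median was 0.26 with both trends removed. CYP1A1 (−0.42), CYP1B1 (−0.71), CXCL8 (0.66) and HMGCS1 (−0.44) were not called, but without CQWIN 1 CYP1B1 (−0.84) and CXCL8 (1.10) were.

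No further gene was called: edgeR called 2 in CDWIN against CQWIN, of 2473 at an unadjusted p under 0.05, and DESeq2 called 29. Without CQWIN 1 there were 1885 calls, and without CDWIN 1, CDWIN 2 or CDWIN 3 there were 0.

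The interaction asked whether the WIN minus SUM difference was the same for CD and CQ. For VPS35 this difference was higher in CD by 2.63 ± 0.41 (adjusted p = 0.0115). For SCD it was lower in CD by −0.95 ± 0.23 (adjusted p = 0.0419): SCD averaged 278 ± 27.5 CPM in CDSUM and 351 ± 41.4 in CDWIN, against 333 ± 41.5 in CQSUM and 813 ± 164 in CQWIN (n = 3 each). VPS35 was not called without CDSUM 2 (2.57) or CDWIN 3 (2.5). SCD was called with CDWIN 2, CQWIN 1 or CQWIN 2 left out, but not without CDSUM 1 (−1.0), CDSUM 2 (−0.97), CDSUM 3 (−0.86), CDWIN 1 (−1.01), CDWIN 3 (−0.98), CQSUM 1 (−1.01), CQSUM 2 (−0.85), CQSUM 3 (−0.99) or CQWIN 3 (−0.82). The inflammatory list had no interaction call (adjusted p = 0.869), nor did CYP1A1 (−0.94), CXCL8 (0.26) or HMGCS1 (0.33), but CYP1A1 was called without a filter on low counts (−1.13).

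For the interaction edgeR called 315 genes, 309 higher and 6 lower, of 1971 at an unadjusted p under 0.05. DESeq2 called 540, and 135 were called with GC and length trends removed, of which 109 were among the 315. The count was 0 without CDSUM 2 or CDWIN 3 (1720 and 1566 at an unadjusted p under 0.05). It was 206 without CDSUM 1, 30 without CDSUM 3, 24 without CDWIN 1, 883 without CDWIN 2, 58 without CQSUM 1, 25 without CQSUM 3 and 24 without CQWIN 3.

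Of the 216 list tests 62 were called with the preset correlation. Among these, 3 held with an estimated correlation: cholesterol synthesis in CQWIN against DMSO, and cholesterol synthesis and fatty acid synthesis in CQWIN against CQSUM. In none of the 62 called tests did the median, the mean and the test differ in sign.

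In the authors' deposited table the adjusted p-value was under 0.05 for 7425 genes in CDSUM, 6277 in CDWIN, 5877 in CQSUM and 3092 in CQWIN against DMSO. Among the genes called in the authors' deposited table, 5993, 5712, 4859 and 3030 were also called by edgeR here, each in the same direction. The authors tested 23564 to 24890 genes per comparison, against 15565 here, so some of their calls can be genes not tested here. Their calls, higher and lower, were 3740 and 3685 in CDSUM, 3166 and 3111 in CDWIN, 2852 and 3025 in CQSUM and 1304 and 1788 in CQWIN. For CDSUM edgeR here had 2381 higher and 4858 lower, so the excess of lower genes differed. Between PM2.5 groups the counts from the authors' deposited table were 1608 for CDWIN against CDSUM, 3 for CQWIN against CQSUM, 3088 for CDSUM against CQSUM and 2 for CDWIN against CQWIN. Among these calls of the authors' deposited table, 1198, 3, 2055 and 2 were also called by edgeR here. The authors had 774 higher and 2314 lower in CDSUM against CQSUM, and 1465 and 143 in CDWIN against CDSUM. The counts by edgeR here were 26 and 2130, and 1272 and 38.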

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

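The test of whether the WIN minus SUM difference was the same for CD and CQ was fixed in advance. The test of a difference in depth between CDSUM and CQSUM was chosen only after the result was seen.

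In total 315 genes had a WIN minus SUM difference that differed between CD and CQ, 309 of them with a higher value in CD. The 5 largest positive values were in VPS35 (2.63 ± 0.41), NUP107, a nuclear pore gene (2.43 ± 0.50), the zinc transporter gene SLC39A10 (2.38 ± 0.60), RARS, the arginyl-tRNA synthetase gene (2.31 ± 0.40), and the splicing factor gene SF3B1 (2.31 ± 0.44). The largest negative values were in the kinase gene MAP3K3 (−0.95 ± 0.23) and in SCD (−0.95 ± 0.23). The 5 genes with the largest positive values all had their lowest group mean in CDSUM. VPS35 averaged 20.4 CPM there, against 98.6 in DMSO, 135 in CDWIN, 152 in CQSUM and 163 in CQWIN. For SF3B1 the same means were 25.6, 117, 129, 161 and 163 CPM. The CDSUM libraries also enter CDWIN against CDSUM and CDSUM against CQSUM, so these results are not independent. With the GC trend removed the interaction gave 56 genes, and removing it can also remove real change. With GC and length trends removed SLC39A10 and MAP3K3 were not called, and the values of VPS35, NUP107, RARS, SF3B1 and SCD were 2.18, 1.90, 1.82, 1.81 and −0.90. RARS was not called without CDSUM 2 (2.28), CDWIN 3 (2.27) or CQWIN 3 (2.19), and VPS35 was not called without CDSUM 2 (2.57) or CDWIN 3 (2.5). SF3B1 was not called without CDSUM 2 (2.22), CDSUM 3 (2.31), CDWIN 1 (1.97), CDWIN 3 (2.25), CQSUM 3 (2.26) or CQWIN 3 (2.27). NUP107 was not called without CDSUM 2 (2.53), CDSUM 3 (2.39), CDWIN 1 (2.02), CDWIN 3 (2.40), CQSUM 1 (2.16), CQSUM 3 (2.40) or CQWIN 3 (2.41). SLC39A10 was called only with CDWIN 2, CQSUM 2 or CQWIN 2 left out, and MAP3K3 only with CDWIN 2, CQWIN 1 or CQWIN 2 left out.

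Of 25 cell cycle genes 3 had a higher difference in CD and none a lower, or 4 adjusted over the list alone (median 0.462, adjusted p = 5.78e-05, and adjusted p = 0.662 with an estimated correlation). Of 25 DNA replication genes 2 had a higher difference and none a lower, or 4 adjusted over the list alone (median 0.173, adjusted p = 0.0342, and adjusted p = 0.73 with an estimated correlation). The DNA replication call was lost without CDSUM 3 (0.11), CDWIN 2 (0.17), CDWIN 3 (0.15), CQSUM 2 (0.13), CQWIN 1 (0.22) or CQWIN 3 (0.12). Of 23 cholesterol synthesis genes none was called and 3 had a lower difference adjusted over the list alone (median −0.191, adjusted p = 0.00755, and adjusted p = 0.66 with an estimated correlation), a call lost without CDWIN 2 (−0.17) or CQWIN 1 (−0.04). Of 16 fatty acid genes 1, SCD, had a lower difference, or 1 higher and 2 lower adjusted over the list alone (median −0.235, adjusted p = 0.00138, and adjusted p = 0.66 with an estimated correlation).

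Of 100 splits of the 12 PM2.5 libraries 4, the real one included, gave at least as many interaction calls as the real 315, and the highest other count was 2134. The real count lies within the range of these splits, so chance is left open. A split can also carry differences between the groups themselves into this contrast. The count of 2134 therefore does not tell whether the libraries hold a structure beyond the groups. Without CDSUM 2 or CDWIN 3 no gene was called by edgeR (1720 and 1566 at an unadjusted p under 0.05). VPS35 was at 18 to 24.5 CPM in the CDSUM libraries and at 63.4 CPM in CDWIN 2, against 159 and 183 CPM in the other CDWIN libraries.

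Most genes called between CDSUM and CQSUM were lower in CDSUM, KNTC1, RECQL and RAD17 among them. With the GC trend of each library removed 890 of the 2130 lower genes were still called, and their median log2 fold change moved from −1.28 to −0.77, so a GC trend could account for a large part of these calls, but the GC slope was positive in all CDSUM and negative in all CQSUM libraries, and removing it can also remove real change. The lower genes had a median GC content of 40.6%, against 49.8% for all genes tested. They were also longer, with a median transcript length of 4390 bases against 2780, so a length trend can have a part. With the length trend removed 1873 were still called, so the trend with length as fitted here does not account for most of them. How fully the fit removes a length effect in these libraries is not known. A difference in depth is excluded, because total counts of the groups differed by −0.343%.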

How the results depend on the processing

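For CYP1A1, INSIG1, CXCL8 and ID4 every change of method left the call against DMSO in place. The counts of genes called against DMSO moved more. With 1 CDWIN library, assumed to vary like the libraries of the other groups, CDWIN against DMSO gave 3785 genes for CDWIN 1, 1488 for CDWIN 2 and 4250 for CDWIN 3. CQSUM against DMSO gave 2576 with GC and length trends removed, 3201 without DMSO 1, 3049 without CQSUM 2 and 4520 without CQSUM 1. CQWIN against DMSO gave 2249 with only the compared groups in the fit, 2329 with both trends removed, 2485 with the GC trend removed, 2657 without DMSO 1, 2511 without CQWIN 1 and 6102 without CQWIN 3. Genes called in all 4 comparisons numbered 1570 with only the compared groups in each fit, 1244 with both trends removed, 1733 with the GC trend removed, 1584 without DMSO 1, 1783 without CQWIN 1, 3811 without CQWIN 3 and 4195 without CDWIN 2 and CQWIN 3.

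CDWIN against CDSUM, where VPS35 had the largest increase, gave 673 genes with both trends removed, 485 with the GC trend removed, 2187 without CDWIN 2 and CQWIN 3, and 1064, 2 and 1131 with CDWIN 1, 2 and 3 as the only CDWIN library. It gave 857, 663 and 725 without CDSUM 1, 2 and 3, 554 without CDWIN 1, 1866 without CDWIN 2 and 578 without CDWIN 3. CDSUM against CQSUM gave 1275 with the GC trend removed.

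CQWIN against CQSUM, where SCD, FADS1 and ID3 were called, gave 1 gene with the size factors of DESeq2, 42 without a filter on low counts, 11 with DESeq2, 12 with both trends removed, 8 with the GC trend removed and 6 with the length trend removed. It gave 0 with edgeR on only the compared groups (296 at an unadjusted p under 0.05), 0 without CQSUM 2 or CQSUM 3 (341 and 557), 1 without CQSUM 1 and 11 without CQWIN 2.

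CDWIN against CQWIN, where ID3 and SCD were called, gave 1 gene with the size factors of DESeq2, 522 without a filter on low counts, 4 with a block by replicate number, 29 with DESeq2, 7 with both trends removed and 8 with the length trend removed. It gave 0 with edgeR on only the compared groups (1233 at an unadjusted p under 0.05), 0 without CDWIN 2 and CQWIN 3 (620), 0 without CDWIN 1, CDWIN 2 or CDWIN 3 (2379, 1598 and 2420), and 1885 without CQWIN 1.

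The interaction, with VPS35 on top, gave 569 genes without a filter on low counts, 48 with only the compared groups in the fit, 540 with DESeq2, 135 with both trends removed, 56 with the GC trend removed and 896 without CDWIN 2 and CQWIN 3. It was not fitted on 1 side of the GC trend, since its groups lie on both sides. It gave 206, 0 and 30 without CDSUM 1, 2 and 3, 24, 883 and 0 without CDWIN 1, 2 and 3, 58 and 25 without CQSUM 1 and CQSUM 3, and 24 without CQWIN 3.

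Some genes and lists changed sign, but no value of changed sign was called. In CDSUM against DMSO MT2A was −0.11 with the length trend removed, MT1X −0.119 with both trends removed and −0.163 with the length trend removed, and GPX4 −0.03 with the length trend removed. With both trends removed RPS6 was −0.01 in CQSUM and −0.025 in CQWIN, and ABCA3 was 0.001 in CQSUM, each against DMSO. In CQWIN against CQSUM the ribosomal protein median was 0.048 without CDWIN 2 and CQWIN 3, 0.043 without CQWIN 3 and −0.441 without CQWIN 1. The NRF2 target median there was −0.106 without CQWIN 1 and 0.166 without CQWIN 2. The median of nuclear oxidative phosphorylation genes there was 0.063 without CDWIN 2 and CQWIN 3, 0.051 without CQSUM 2, 0.055 without CQWIN 3 and −0.305 without CQWIN 1. Of the values of named genes, removal of both trends left 446 on the same side of the threshold of an adjusted p of 0.05, whatever the change in size, ended the call of 69, added a call for 5 and turned the sign of 4 called values.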

Other observations

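Some gene groups not described above also had members that changed against DMSO. Of 23 apoptosis regulators 7 rose and 6 fell in CDSUM, 7 and 3 in CDWIN, 6 and 2 in CQSUM and 6 and 1 in CQWIN, each the same adjusted over the list alone (adjusted p = 0.0779, 0.187, 0.0501 and 0.0762). The list was called in CDSUM, CQSUM and CQWIN with GC and length trends removed (adjusted p = 0.00837, 0.0108 and 0.0312, and adjusted p = 0.311, 0.348 and 0.395 with an estimated correlation). BCL2A1, a survival factor induced in inflammation, rose 5.05-fold in CDSUM, 4.95-fold in CDWIN, 3.74-fold in CQSUM and 2.37-fold in CQWIN. With both trends removed it was 3.46-fold, 2.56-fold and 2.06-fold higher in the first 3 and not called in CQWIN (0.52). Of 23 autophagy and lysosome genes 7 rose and 3 fell in CDSUM, the same adjusted over the list alone (adjusted p = 0.0554), and 8 rose and 2 fell in CQWIN, or 10 and 2 adjusted over the list alone (adjusted p = 0.0674), a list called in CQWIN with both trends removed (adjusted p = 0.00469, and adjusted p = 0.455 with an estimated correlation). The lysosomal protease gene CTSL rose 2.77-fold in CDSUM, 2.86-fold in CDWIN, 2.22-fold in CQSUM and 2.72-fold in CQWIN. Of 18 iron genes 3 rose and 3 fell in CDSUM, or 2 and 2 adjusted over the list alone (adjusted p = 0.628), where the median was −0.03 and the test pointed up. IREB2, which senses iron, was 3.33-fold lower in CDSUM (−1.74, and −1.16 with both trends removed) and the transferrin receptor gene TFRC 2.4-fold lower (−1.26, and −0.83). TFRC was higher in CQWIN (0.78, adjusted p = 0.0192) and not called in CDWIN (0.45) or CQSUM (0.47), and IREB2 was not called in CDWIN (−0.49), CQSUM (−0.02) or CQWIN (−0.04), though it was in CDWIN with both trends removed (−0.52).

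Of 21 complement and coagulation genes 3 rose and 4 fell in CDSUM, the same adjusted over the list alone (adjusted p = 0.932), where the median was −0.35 and the test pointed up. THBD, the thrombomodulin gene, was 2.84-fold lower in CDSUM, 2.73-fold in CDWIN, 2.8-fold in CQSUM and 2.39-fold in CQWIN. Of 14 fibroblast and endothelial markers 3 were measured, and of 16 leukocyte markers 2 were, too few to test. The 3 fibroblast and endothelial markers gave an adjusted p = 0.932 in CDSUM, with 1 lower over all genes, COL1A1 (−0.75), and none adjusted over the list alone. COL1A1 was not called with both trends removed (−0.07), without DMSO 3 (−0.47) or without CDSUM 1 (−0.72), CDSUM 2 (−0.75) or CDSUM 3 (−0.75). It was also lower in CQSUM (−1.04) and CQWIN (−1.46), but not called in either with both trends removed (−0.25 and −0.73), nor in CQSUM without DMSO 3 (−0.76) or CQSUM 2 (−0.87). LUM, another of the 3 markers, went the other way in CQWIN (2.21), from 0.167 to 0.805 CPM. It was called there, but not with both trends removed (1.81).

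The tests of a mislabelled DMSO library and of mixing with DMSO RNA were chosen only after the result was seen.

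Cholesterol synthesis genes, INSIG1 and MSMO1 among them, were called higher than DMSO as a list in all 4 PM2.5 groups with the preset correlation. With an estimated correlation only CQWIN held (adjusted p = 0.00354), against adjusted p = 0.231 in CDSUM, 0.0524 in CDWIN and 0.107 in CQSUM. The trends with GC content and length as fitted here do not account for the list medians: the lowest ratio of the median with the trends removed to the median as tested was 0.95. How fully the fit removes such trends is not known. A single library is excluded as the cause of the calls with the preset correlation, because the highest adjusted p with 1 library left out was 7.87e-05. The medians then ran from 0.319 to 0.426 in CDSUM, 0.7 to 0.975 in CDWIN, 0.54 to 0.698 in CQSUM and 1.108 to 1.434 in CQWIN.

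CQWIN 3 lay nearer to the DMSO libraries than any other PM2.5 library, at a distance of 0.595. A mislabelled DMSO library is excluded, because CYP1A1, CYP1B1, TIPARP and INSIG1 in CQWIN 3 lay at least 2.35 log2 units above the highest DMSO library plus the DMSO range. Mixing with DMSO RNA might still play a part, though none of these genes lay below both other CQWIN libraries. CYP1A1 was −0.125 log2 units from the higher of the other 2 and above the lower (4.331 against 2.907 log2 CPM). CYP1B1 (0.906), TIPARP (0.143) and INSIG1 (0.031) lay above both. The level of these genes in CQWIN 3 without mixing is not known, so the test cannot tell. The trends with GC content and length as fitted here are not the whole cause. For CQWIN 3 the ratio of its distance to CQWIN over that to DMSO was 1.05 as measured and 1.06 with the trends removed. How fully the fit removes such trends is not known.

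Each comparison of a PM2.5 group with DMSO, INSIG1 and CYP1A1 included, rests on 10 possible splits of 6 libraries, too few for a share under 0.05. The real split was the only 1 with at least as many calls for CDSUM (7239), CDWIN (6493), CQSUM (5061) and CQWIN (4264), and the highest other count was 0. The same holds for CDSUM against CQSUM (2156, highest other 0), CDWIN against CQWIN (2, highest other 0) and CDWIN against CDSUM (1310, highest other 1). For CQWIN against CQSUM 2 splits gave at least the real 3 calls, the highest other with 971. That split set CQWIN 1, CQSUM 2 and CQSUM 3 against CQSUM 1, CQWIN 2 and CQWIN 3. It followed the length slope of the libraries rather than the groups. The slopes were −0.125, −0.12 and 0.0237 on the first side and 0.0637, 0.046 and 0.228 on the second. Whether the length trend accounts for the 971 calls was not tested. For genes called in all 4 comparisons 1 of 100 splits, the real one, reached 2740 calls, a share under 0.05. The highest other, which kept the 3 DMSO libraries together, had 2567, and the median of the others was 0. The share therefore concerns mainly the DMSO libraries against the rest. For the grouping of the PM2.5 libraries among themselves it cannot decide, and chance is left open.

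The 4 comparisons with DMSO share 3 control libraries, so genes such as CYP1A1 and ID4 are not tested independently in each. The covariance of log2 fold changes was 0.434, against 0.0646 in simulated groups that did not change and shared simulated controls, a difference of 0.369. Those simulations held no GC or length trend. The controls are too few to be divided with 2 libraries on each side, and part of the overlap can come from their sharing.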
